A study of Oryzias latipes with 4 samples.

How the data were processed

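Per the labels' protocols, total RNA was taken from medaka embryos by acid guanidinium, phenol and chloroform extraction, the RNA of 4 embryos was pooled and column-purified, and 150 ng was converted to cDNA and transcribed with Cy3-CTP for 1-colour Agilent arrays. The series' design text says that the experiment was done independently for each replicate. The samples fall into 2 groups of 2, ATF6α and ATF6β double knockout and double heterozygous control, taken from the sample titles.

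The deposited scanner tables hold spot intensity values, made by the authors with Agilent's Feature Extraction software, per the file headers. The processed signal in them is already background-subtracted by that software. The deposited series matrix holds log2 values of the same arrays. Set against each array's scanner values, they differed from the log2 processed signal by 1 constant per array that matches the 75th percentile, so scale and centring are known and the columns run in the same direction; their medians were -2.43, -2.44, -2.46 and -2.47. No aligner or genome build applies.

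Each array held 45220 spots, of which 43803 were not controls, for 26439 probes. Control spots were left out, as were spots marked as non-uniform outliers (18 and 26 on the arrays labelled double knockout, 10 and 2 on the control arrays). No such spot was a population outlier or saturated. The log2 processed signal was averaged over the spots of a probe, and the array's 75th percentile over non-control probes was subtracted. A probe was tested when it was well above background on both arrays of at least 1 group, which kept 22446 probes. The standard deviation between duplicate spots and the number of arrays limit the precision.

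Gene names come from the scanner files. Of the probes on the array 23138 carry an Ensembl gene ID, and 7122 of the tested probes carry a product name from an orthology group or a vertebrate protein. The given reference table of gene symbols holds no Ensembl IDs for this species, so none matched and product names are printed as the files give them. An orthology name can cover several paralogs, and several medaka genes can share it. No probe name tells ATF6α from ATF6β. Broad families such as the eIF2α kinases were not assigned to a list member, so PERK was not analysed here. A gene took its probe with the highest mean signal. Of 218 genes with several tested probes and at least 1 that passed, all probes went the same way in 203 and all passed in 98. Each gene said to have risen or fallen that had several tested probes passed on all of them in the same direction. The probes of the site-1 protease, which did not pass, had changes of -0.07 and 0.02.

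The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom and a prior of 3.26), two-sided, with Benjamini-Hochberg adjustment over the probes and a threshold of 0.05. SE is limma's moderated standard error, with a median of 0.102. Where a probe was not well above background on any array of a group, the fold is given as a bound, the brighter group's mean against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. The 26 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Camera asks whether a list moves against the other genes. The rule named ATF6 and the other sensors, the 12 largest rises and 12 largest falls in fitted log2 change among named genes that passed without overlap, and for each list the passing members of smallest p, up to 4, or up to 6 where the list was called, or 2 with their values where none passed. For some lists the text prints only the first of these, in order of p.

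The procedure was tested on simulated data for this comparison, with 22446 probes, 200 of them changed, in 20 runs. With spreads drawn from the fitted prior it recovered 72.2%, 97.5% and 99.6% of log2 changes of 1, 2 and 3, and 5.28% of calls were false. With each probe's own shrunken spread it recovered 97.8%, 99.8% and 100%, and 10.1% of calls were false. On 19954 genes, each simulated independently of the others, camera at the preset correlation called 2 of 520 tests of lists without a shift. It called a shift of -0.5 in the ER chaperones in 20 of 20 runs. With an estimated correlation that shift was called in 0 of 20. These runs do not test camera where the genes of a list move together. In the real data the estimated correlation ran from -0.15 (sensors) to 0.919 (lens and retina) over the lists. Alternatives were the background correction, the normalization, the filter on dim probes, the model of the spread, the replicate number as a block, each replicate left out, the threshold, the probe taken per gene and the set test.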

Results

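Whole embryos of medaka (Oryzias latipes, a small freshwater teleost) of the Kyoto Cab strain were profiled at stage 24, 2 days after fertilisation. Per the labels, one group carried disrupted copies of both ATF6 homologues (ATF6α and ATF6β) on both chromosomes and is called double knockout. The other was heterozygous at both genes and served as the control. ATF6 is a membrane-bound transcription factor of the endoplasmic reticulum (ER) that is cleaved when unfolded proteins build up and then induces ER chaperone genes. RNA from 4 embryos was pooled per sample, and each group had 2 samples from independent experiments, hybridised to 1-colour Agilent oligonucleotide arrays. The 75th percentile of the signal was 1318 and 1881 on the arrays labelled double knockout and 1657 and 1626 on the control arrays. Between 83.4% and 86.3% of the 26439 probes were well above background on an array. Over the 22446 tested probes the first principal component separated the labelled groups, and the others held 18.1% and 11.8% of the variance. The number of arrays limits the precision, and every value has n = 2 per group.

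The targeted gene was examined first. A pair of probes carried the name activating transcription factor 6 (ENSORLG00000016676), with no mention of α or β, and both gave more signal in the embryos labelled double knockout. Both belong to this 1 gene, and no probe was named for a second ATF6 homologue. The brighter probe read -1.19 and -1.39 in double knockout replicates 1 and 2 and -2.37 and -2.41 in control replicates 1 and 2, in log2 units relative to the array's 75th percentile. It was 2.14-fold higher in the embryos labelled double knockout (log2 change 1.10, SE 0.10, adjusted p = 0.00907). The dimmer probe read -3.12 and -3.03 against -3.96 and -3.78, a 1.74-fold difference (log2 change 0.80, SE 0.10, adjusted p = 0.0185). The sources used here do not give the disrupted part of either gene or the place of these probes in the transcript. A probe outside the disrupted part checks nothing, so the labels stand unchecked by the targeted gene, and each direction given here is that of the arrays as labelled. With control replicate 1 or 2 left out, the brighter probe's change was 1.12 or 1.08 and missed the threshold (adjusted p = 0.0720 and 0.0620). The dimmer probe missed it there too (adjusted p = 0.109 and 0.0664) and with no filter on dim probes (adjusted p = 0.0581).

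**Figure D1:**
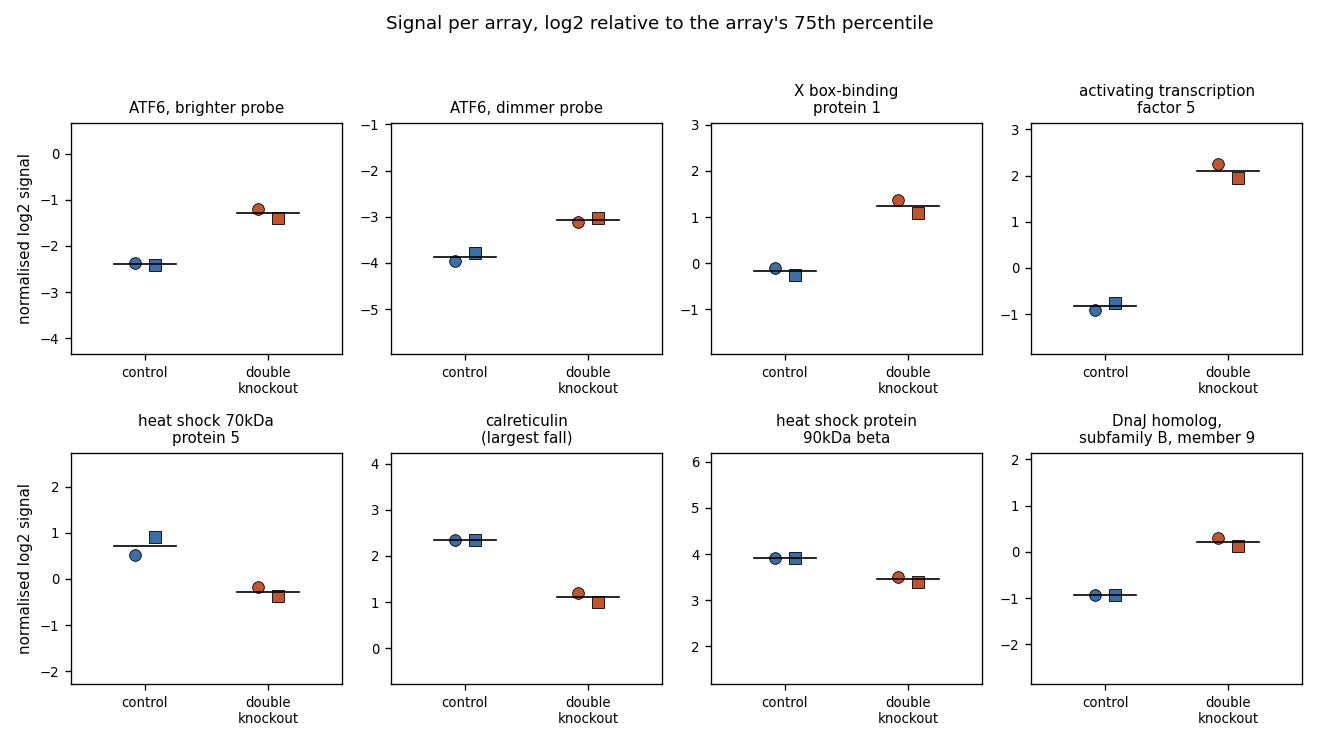
Normalised log2 signal per array (vertical axis, log2 units relative to each array's 75th percentile, the same height in every panel) in the 2 control samples (blue) and the 2 samples labelled double knockout (orange), with circles for replicate 1, squares for replicate 2 and a line at the group mean. Both ATF6 probes, X box-binding protein 1, activating transcription factor 5 and DnaJ homolog B9 lie higher in the samples labelled double knockout, and heat shock 70kDa protein 5, the calreticulin gene with the larger fall and heat shock protein 90kDa beta lie lower.

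The comparison asked which genes differ between the embryos labelled double knockout and the double-heterozygous controls. Of 22446 probes tested (19954 genes), 1698 passed, 1116 higher and 582 lower in the embryos labelled double knockout. Of 28 measured genes of the PERK-ATF4 and integrated stress response 19 rose, and of 26 somite and muscle genes 11 fell. Activating transcription factor 5, a stress-induced transcription factor, rose 7.64-fold (log2 change 2.93, SE 0.14, adjusted p = 0.00225). Fast skeletal muscle troponin T, a thin-filament regulator of contraction, fell 4.68-fold (log2 change -2.23, SE 0.20, adjusted p = 0.00822). At least 2-fold change was seen for 270 of the probes that rose and 145 of those that fell. Values of the 2 groups did not overlap for 13258 probes, 59.1% of those tested, where chance gives 33.3%.

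Among genes with a product name, the largest rise was that of GABA receptor rho 2, a ligand-gated chloride channel subunit. It was not well above background in either control and was at least 19.7-fold higher in the embryos labelled double knockout. The ubiquitin ligase RNF14 rose 14.7-fold (log2 change 3.88, SE 0.15). The orphan receptor GPR149, not well above background in the controls, rose at least 2.95-fold, and an FLVCR family transporter, in the family of heme exporters, rose at least 4.03-fold. L-asparaginase, which splits asparagine, rose 7.58-fold, and retinal G protein coupled receptor, an opsin of the retinal pigment epithelium, rose 6.56-fold. ChaC, which breaks down glutathione, rose 5.70-fold, and an L-amino acid transporter of the LAT family rose 5.58-fold. A mitochondrial folate enzyme, methylenetetrahydrofolate dehydrogenase (NAD+), rose 5.59-fold. Cytochrome P450 family 3 subfamily A, a drug and steroid oxidase, rose 5.54-fold, and phosphoserine aminotransferase, an enzyme of serine synthesis, rose 5.24-fold. Adjusted p lay between 0.00108 and 0.00599 for these 12 genes, activating transcription factor 5 included.

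Most of the 12 named genes with the lowest fitted log2 changes were not well above background in the embryos labelled double knockout, and their falls, known only as bounds, have no order. Besides fast troponin T, a myosin light chain 1 gene was measured in all samples and fell 3.87-fold (log2 change -1.95, SE 0.19). Another myosin light chain 1 gene was at least 2.20-fold higher in the controls. A pair of genes named homeobox HoxA/C/D13, posterior patterning factors, were at least 1.84-fold and 2.38-fold higher in the controls. The AP-1 adaptor subunit sigma-3, part of a vesicle coat, was at least 3.19-fold higher in the controls, and receptor activity modifying protein 1, a partner of calcitonin-family receptors, at least 2.96-fold. Galactosylceramide sulfotransferase, TSPY-like 2, endothelin and an alpha-kinase were at least 1.70-fold, 1.62-fold, 1.51-fold and 1.29-fold higher in the controls. An astacin protease fell (fitted log2 change -2.31, SE 0.42) and was well above background in 1 of the 2 samples labelled double knockout, so its fold is uncertain. Adjusted p lay between 0.0019 and 0.0399 for these 12 genes, fast troponin T included. With a normexp background, 5 of these dim genes changed sign without passing: the HoxA/C/D13 gene with the bound of 1.84-fold, galactosylceramide sulfotransferase, TSPY-like 2, endothelin and the alpha-kinase. Neither gene of the HoxA/C/D13 pair passed there. Over all 82 named genes that passed, those of the lists included, that background kept 52 of 52 rises but only 17 of 30 falls.

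Of 7 measured sensors and transcription factors of the unfolded protein response, 2 rose, ATF6 and X box-binding protein 1, and none fell, while 4 rose when adjusted over the list alone. X box-binding protein 1, the transcription factor that the sensor IRE1 activates by splicing, rose 2.65-fold (log2 change 1.41, SE 0.13, adjusted p = 0.0084). IRE1 itself had a log2 change of -0.18 (SE 0.09, adjusted p = 0.262), and the site-1 and site-2 proteases that cleave ATF6 had changes of -0.07 and 0.05. A pair of CREB3-family genes, cleaved by the same proteases, had changes of 0.55 (SE 0.12) and 0.25 (SE 0.08). The list, which counts the targeted ATF6 itself, shifted upwards with a median of 0.25 (camera adjusted p = 0.0484) and was not tested without ATF6. The call was lost with an estimated correlation (adjusted p = 0.322). That adjusted p of 0.322 was also the value for each of the other called lists except the notochord sheath matrix. In the simulated data, camera with an estimated correlation called a shift of -0.5 in 0 of 20 runs. For a shift of that size in genes that vary independently, the loss of a call there therefore cannot tell a true shift from none. Larger list shifts, and lists whose genes move together, were not simulated. The call of the sensor list also ended without double knockout replicate 2 or control replicate 2 (adjusted p = 0.0667 and 0.0732), with quantile normalization and with no filter on dim probes (adjusted p = 0.0513 and 0.231).

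ER chaperones and folding enzymes moved both ways. Of 28 measured members, 8 rose and 4 fell, and adjusted over the list alone 10 rose and 4 fell. The HSPA13-type stress 70 chaperone of microsomes rose 2.89-fold (log2 change 1.53, SE 0.08, adjusted p = 0.00329). Prolyl 4-hydroxylase beta, which is protein disulfide isomerase, rose 2.74-fold, and the ER co-chaperone DnaJ homolog B9 rose 2.21-fold. The 4 members that fell are named after their values were seen, except the first. A calreticulin gene, a lectin chaperone of glycoproteins, fell 2.36-fold (log2 change -1.24, SE 0.10, adjusted p = 0.00719), and another calreticulin gene fell 1.96-fold (adjusted p = 0.00843). Heat shock 70kDa protein 5, known as BiP and the main lumenal chaperone, fell 1.99-fold (log2 change -0.99, SE 0.15, adjusted p = 0.0281). Heat shock protein 90kDa beta, known as GRP94, fell 1.38-fold (log2 change -0.46, SE 0.09, adjusted p = 0.0441). The list as a whole showed no shift (median 0.08, camera adjusted p = 0.249; adjusted p = 0.701 with an estimated correlation). With all probes tested whatever their brightness, 5 members passed, and with control replicate 1 or 2 left out, 1 and 2 members passed, all higher.

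The lists of protein entry into the ER, N-glycosylation, ER-associated degradation and COPI and COPII transport were called higher by camera at the preset correlation. None of the 4 calls held with an estimated correlation (adjusted p = 0.322), a version that called the simulated shift in 0 of 20 runs. In the list of translocon, signal peptidase and signal recognition genes, 9 of 15 members rose, 12 adjusted over the list alone, and none fell (median 0.72, camera adjusted p = 1.78e-09). That p assumes the preset correlation of 0.01, while the estimated correlation of this list was 0.457. The signal recognition particle receptor rose 2.22-fold (log2 change 1.15, SE 0.08), an alpha subunit of the SEC61 channel 2.26-fold, signal sequence receptor delta 2.00-fold and the SEC61 beta subunit 2.20-fold. Of 23 N-glycosylation genes, 8 rose, 12 adjusted over the list alone, and none fell (median 0.31, camera adjusted p = 8.5e-06). Dolichyl-phosphate mannosyltransferase polypeptide 3, dolichyl-phosphate beta-glucosyltransferase and beta-1,4-mannosyltransferase, of lipid-linked sugar synthesis, rose 1.89-fold, 2.06-fold and 2.15-fold. Of 11 ER-associated degradation genes, 4 rose and none fell, and the same counts held adjusted over the list alone (median 0.13, camera adjusted p = 0.0218). The mannosidase-like factor EDEM rose 2.03-fold, the ubiquitin ligase RNF5 rose 1.70-fold and Derlin-1, a part of the retrotranslocation channel, rose 1.65-fold. The 7 measured genes of the COPI and COPII transport list were lectins mannose-binding 1 and 2, ER lumen protein retaining receptors, coatomer alpha and ADP-ribosylation factor 1. No COPII coat gene was among them. Lectin mannose-binding 1, a cargo receptor that carries glycoproteins out of the ER, rose 3.12-fold and was the only member to pass. Adjusted over the list alone 2 rose (median 0.24, camera adjusted p = 0.00551). The call of ER-associated degradation also ended without double knockout replicate 1 or control replicate 2 (adjusted p = 0.0514 and 0.0732) and with the mean of a gene's probes (adjusted p = 0.0512).

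The PERK-ATF4 and integrated stress response list had the largest shift (median 0.85, camera adjusted p = 7.5e-13 at the preset correlation of 0.01). With its estimated correlation of 0.215 the camera adjusted p was 0.322. Of its 28 measured members 19 rose and none fell, and adjusted over the list alone 21 rose and 1 fell. Besides the genes of the largest rises, cystathionine gamma-lyase, which makes cysteine, rose 3.49-fold (log2 change 1.80, SE 0.11, adjusted p = 0.00432). Asparagine synthase rose 3.17-fold (log2 change 1.66, SE 0.13), and C/EBP gamma, a dimer partner of ATF4, rose 2.51-fold (log2 change 1.33, SE 0.09). Genes of cholesterol and fatty acid synthesis rose in 6 of 23 cases, 11 adjusted over the list alone, and none fell (median 0.39, camera adjusted p = 0.000955; adjusted p = 0.322 with an estimated correlation and 0.0783 with fry). Fatty acid synthase rose 2.32-fold and sterol regulatory element-binding transcription factor 1, a regulator of this pathway, rose 1.56-fold.

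**Figure D2:**
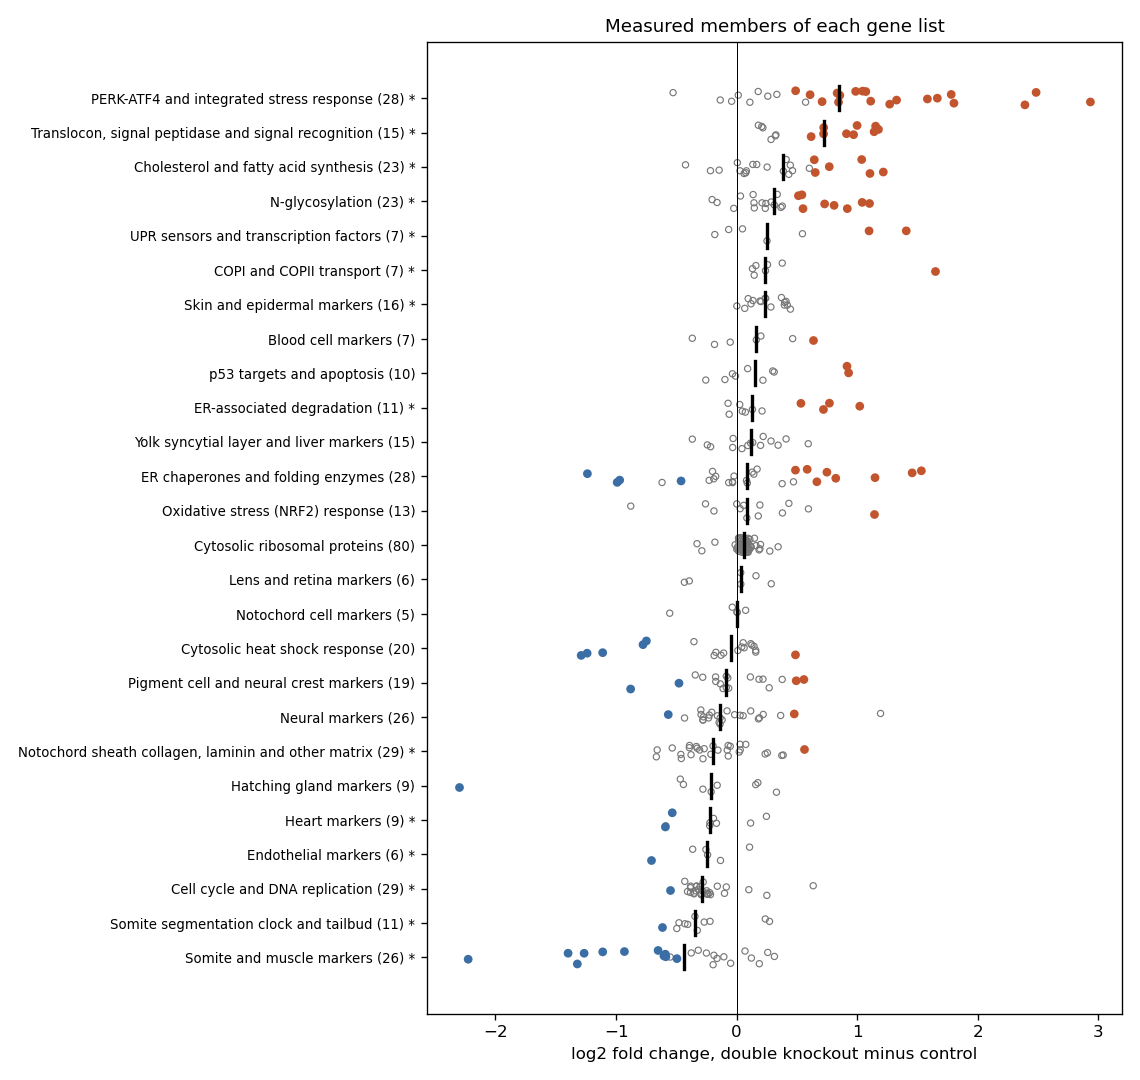
Log2 fold change, samples labelled double knockout minus control (horizontal axis), of each measured member of the 26 gene lists, with the number measured in brackets. Filled points passed the limma test (orange higher, blue lower), open points did not, black bars mark the list's median and a star marks lists called by camera at the preset correlation. Medians run from -0.44 for somite and muscle markers to 0.85 for the integrated stress response, and the ER chaperones hold filled points on both sides of 0.

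Heat shock, NRF2, p53 and ribosomal protein lists were not called by camera. Among 20 heat shock members, 5 fell and 1 rose, with the same counts adjusted over the list alone (median -0.05, camera adjusted p = 0.112). The riser was serpin peptidase inhibitor clade H member 1 (log2 change 0.49, SE 0.10, limma adjusted p = 0.0472), which the ER chaperone list names too. A pair of heat shock 70kDa protein 1/8 genes fell 2.36-fold and 2.44-fold, an HSP90 gene (molecular chaperone HtpG) fell 2.16-fold and the small heat shock protein 8 fell 1.68-fold. The heat shock list was called lower with a normexp background and without double knockout replicate 1 or control replicate 2 (adjusted p = 0.0094, 0.0479 and 0.0136). In the NRF2 list of 13 members, 1 rose, 2 adjusted over the list alone. It was NRF2 itself, the regulator of antioxidant genes, which rose 2.20-fold (median of the list 0.08, camera adjusted p = 0.18). Of 10 p53 and apoptosis genes 2 rose, also adjusted over the list alone: caspase 9 by 1.90-fold and caspase 8 by 1.89-fold (median 0.15, camera adjusted p = 0.101), and fry called this list higher (adjusted p = 0.0473). Of 80 cytosolic ribosomal protein genes none passed, nor any adjusted over the list alone. Their median was 0.06 (camera adjusted p = 0.151), and the lowest p values belonged to a pair of S27e genes with changes of -0.33 and -0.29. The ribosomal list was called higher without double knockout replicate 2 by camera at the preset correlation of 0.01 (mean change 0.168). Over all arrays its estimated correlation was 0.836. Neither camera at that correlation nor fry called it (adjusted p = 0.845 and 0.670).

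The lists of somite and muscle, segmentation clock, heart, endothelial and cell cycle genes were called lower in the embryos labelled double knockout by camera at the preset correlation. None of the 5 calls held with an estimated correlation (adjusted p = 0.322), a version that called the simulated shift in 0 of 20 runs. The segmentation clock call ended without control replicate 2 (mean change -0.20, against -0.28 with all arrays). Of 26 somite and muscle genes 11 fell, 13 adjusted over the list alone, and none rose (median -0.44, camera adjusted p = 1.87e-06). The estimated correlation of this list was 0.185, above the preset 0.01. Slow skeletal troponin T fell 2.16-fold (log2 change -1.11, SE 0.10), troponin C of slow and cardiac muscle 2.40-fold, a second fast troponin T 2.64-fold (4.06-fold on its dimmer probe), tropomyosin 3 1.57-fold, and desmin, the muscle intermediate filament, 1.51-fold. Of 11 segmentation clock and tailbud genes 1 fell, 4 adjusted over the list alone, and none rose (median -0.35, camera adjusted p = 0.00816, fry 0.0866). It was a mesoderm posterior gene, which sets somite boundaries and fell 1.53-fold. Among 9 heart genes 2 fell, also adjusted over the list alone, both HAND-family genes needed for heart growth, by 1.45-fold and 1.51-fold (median -0.22, camera adjusted p = 0.0273). Among 6 endothelial genes the vessel receptor TIE1 fell 1.63-fold, with 2 adjusted over the list alone (median -0.25, camera adjusted p = 0.024). Of 29 cell cycle and DNA replication genes 1 fell, a large-subunit ribonucleotide reductase gene by 1.47-fold, while adjusted over the list alone 20 fell and 1 rose (median -0.29, camera adjusted p = 3.15e-07). The heart and endothelial calls ended without control replicate 2 (adjusted p = 0.0619 and 0.0605) and without double knockout replicate 2 (0.0724 and 0.0570). With no filter on dim probes the heart call ended (adjusted p = 0.0520).

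The lists for the notochord and its sheath, a tissue with a high load of secreted collagen, gave a split picture. In RNA of whole embryos the matrix list does not measure the notochord alone. Of 29 sheath collagen, laminin and other matrix genes 1 rose, laminin beta 2 by 1.47-fold, while adjusted over the list alone 2 rose and 6 fell. The list's median was -0.20 (camera adjusted p = 0.0362; adjusted p = 0.653 with an estimated correlation and 0.287 with fry), and the call ended with quantile normalization, with no filter on dim probes and without double knockout replicate 1 or control replicate 2 (adjusted p = 0.0699, 0.0520, 0.211 and 0.0636). None of the 5 notochord cell markers passed, nor adjusted over the list alone. Calymmin had a change of -0.56 (SE 0.19) and brachyury, the notochord transcription factor, of 0.07 (SE 0.15). Their median was 0.00 and their mean -0.10 (camera adjusted p = 0.549).

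Other tissues gave few calls. Epidermal genes shifted upwards as a list (16 measured, median 0.24, camera adjusted p = 0.00167; adjusted p = 0.322 with an estimated correlation), though none passed alone or adjusted over the list alone, and a pair of type II keratins had changes of 0.41 (SE 0.09) and 0.40 (SE 0.10). Of 19 pigment cell and neural crest genes 2 rose and 2 fell, 3 and 3 adjusted over the list alone. GTP cyclohydrolase I and 6-pyruvoyl tetrahydrobiopterin synthase, of pteridine synthesis, fell 1.84-fold and 1.39-fold, and a pair of purine-nucleoside phosphorylases rose 1.41-fold and 1.47-fold (list median -0.09, camera adjusted p = 0.39). Among 26 neural genes neurofilament light chain rose 1.39-fold and an engrailed gene fell 1.48-fold, also adjusted over the list alone (median -0.14, camera adjusted p = 0.249; 0.0405 with a normexp background). RUNX1, a blood stem cell factor, rose 1.55-fold among 7 blood genes, with 2 rising and 1 falling adjusted over the list alone (median 0.16, camera adjusted p = 0.333). The astacin protease was the only one of 9 hatching gland genes to pass, also adjusted over the list alone (median -0.21, camera adjusted p = 0.212). The hatching gland list was called lower with a normexp background and without double knockout replicate 1 (adjusted p = 0.0298 and 0.0348). In the yolk syncytial layer and liver list of 15 and the lens and retina list of 6, none passed, nor adjusted over the list alone. Apolipoprotein E had a change of 0.34 (SE 0.09) and fatty acid-binding protein 3 of -0.37 (SE 0.09) (list median 0.12, camera adjusted p = 0.333). A retinal homeobox gene had a change of 0.29 and the lens protein filensin of -0.43 (list median 0.03 but mean -0.05, camera adjusted p = 0.829).

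The count of 1698 fell to 94 without control replicate 1 and to 225 without control replicate 2, and it was 481 with no filter on dim probes and 4869 with a normexp background. Position on the slide and group cannot be told apart, because all 4 arrays were on 1 slide with the arrays labelled double knockout at positions 1 and 2 and the controls at positions 3 and 4.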

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

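Without 1 replicate, probes called ran from 94 (control replicate 1 out) to 1586 (double knockout replicate 2 out), lists from 9 (control replicate 2 out) to 14, ER chaperones from 1 to 10, named genes that held from 18 to 70 of 82, and the brighter ATF6 probe's log2 change from 0.9999 to 1.20. The brighter ATF6 probe missed the threshold without either control (adjusted p = 0.0720 and 0.0620; 0.000821 to 0.0399 under the other alternatives), and the dimmer probe there (0.109 and 0.0664) and with no filter on dim probes (0.0581). The lone sample is assumed to vary like the other group, and 1 residual degree of freedom is left. A normexp background called 4869 probes, 86.5% of them higher against 65.7%, with the median change of all probes moved to 0.12. It turned the sign of 111 of the 1698 probes, among them 5 named dim genes that then did not pass: HoxA/C/D13 (0.18), galactosylceramide sulfotransferase (0.20), TSPY-like 2 (0.17), endothelin (0.22) and an alpha-kinase (0.19). Of the named genes it kept 52 of 52 rises but only 17 of 30 falls. With no filter on dim probes, 481 probes, 5 ER chaperones and 44 named genes passed, with 26427 probes tested. At an adjusted p under 0.1, 3450 passed, at least 2-fold change left 415, and 309 changed at least 2-fold the same way in both same-numbered pairs. No list was called (0) with an estimated correlation, a version that also called the simulated shift in 0 of 20 runs. Fry called 12 lists. These leave out cholesterol and fatty acid synthesis, the segmentation clock and the notochord sheath matrix (adjusted p = 0.0783, 0.0866 and 0.287) and add p53 (0.0473). All other alternatives kept each count within 1.5 times, among them the 1463 probes (59.3% higher) of quantile normalization and the 1697 of the series matrix. The causes were not tested. Signal over background limits the dimmest probes, whose folds are bounds.

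As to pairing, same-numbered samples did not deviate together (correlation -0.01 over 22446 probes). With the replicate number as a block 1559 probes, 14 lists, 10 ER chaperones and 76 named genes were called, and the brighter ATF6 probe had adjusted p = 0.0117.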

Other observations

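The tests on Hox genes and on aminoacyl-tRNA synthetases, and all tests of explanations except those of signal strength and of the myogenic factor, were chosen after the result was seen. Those exceptions also address patterns already seen. The signal strength tests used lists that camera had called, and the myogenic factor was set against the observed muscle median. Of 33 genes named as aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA, 16 rose and none fell in the embryos labelled double knockout, by log2 changes from 0.49 to 1.59. Among the risen were 6 members of the integrated stress response list and 10 genes outside it, with glutaminyl-tRNA synthetase (log2 change 1.59, SE 0.09) and threonyl-tRNA synthetase (1.26, SE 0.09) the highest. Of 14 such names carried by several genes, exactly 1 gene rose for 13 names and none for 1. The 17 that did not pass lay between -0.21 and 0.33. The files do not tell cytosolic from mitochondrial enzymes. With a normexp background 17 rose, and with quantile normalization, median centring or the series matrix values 16.

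Hox genes pattern the body from head to tail, and differences between their paralog groups were not tested. All 3 measured genes of paralog group 13, the most posterior, passed as lower. One fell by 1.72 on the log2 scale (SE 0.13), and the other 2 were not well above background on the arrays labelled double knockout and at least 1.84-fold and 2.38-fold higher in the controls. Of 9 genes in groups 9 to 12, 2 fell (median -0.19), and of 14 genes in groups 1 to 6 none passed (median 0.00). With a normexp background, which lifts dim signals by its offset, none of the 3 passed and their changes ran from -0.35 to 0.18, the gene measured on all arrays included.

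The ATF6 rise on the arrays labelled double knockout goes against a plain loss of the transcript. An exchange of 1 array between the groups is argued against by the array correlations, whose lowest value within a group exceeded the highest between groups by 0.0048. A single faulty probe is argued against by the second probe, whose log2 change was 0.80 (SE 0.10). That probe's change ran from 0.71 to 0.89 where it missed the threshold, without control replicate 1 or 2 (adjusted p = 0.109 and 0.0664) and with no filter on dim probes (0.0581). A transcript still made, at a higher level, from the disrupted gene that these probes report stays open. The place relative to the disrupted part is known for 0 of the 2 probes. An exchange of the groups' labels as a whole was not tested.

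The split of the ER genes, with BiP, GRP94 and calreticulin lower while translocon and integrated stress response genes were higher, is not made by the scaling of the arrays alone. Under quantile normalization 10 of the 12 called ER chaperones passed in the same direction, 6 higher and 4 lower. For the translocon and integrated stress response lists, a bias that depends on signal strength is argued against by 10000 random lists matched on signal. Of these, 0% had a mean as large as either list. The ER chaperones that fell were not tested against such a bias. A candidate explanation is that the PERK and IRE1 arms of the response were active without ATF6 and induced the genes that rose, while BiP, GRP94 and calreticulin need ATF6. It stays open, because 0 probes are described as telling spliced from unspliced XBP1 and kinase activity was not measured.

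The downward calls of the muscle and segmentation clock lists by camera at the preset correlation may reflect tissue or timing. Fry called the muscle list (adjusted p = 0.0473) but not the segmentation clock list (adjusted p = 0.0866). Signal strength is argued against, since at most 0.28% of 10000 matched random lists had a mean as low. A delay of the whole embryo stays open. Genes taken as late in other tissues (13 genes of neurons, glia, lens and pigment cells) had a median of -0.0861 (95% bootstrap interval over genes -0.16 to 0.16). They went both ways, with neurofilament light chain rising. The interval resamples the chosen genes and does not show the spread between embryo pools. Fewer cells of the muscle lineage also stay open, with the 1 measured myogenic factor gene at -0.0501 (SE 0.09), where the muscle median was -0.44.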
